A study of Rattus norvegicus with 8 samples.

How the data were processed

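RNA from vessels of male rats was measured on 1-colour oligonucleotide microarrays, with 1 array for each of 4 control rats and 4 hypertensive rats. Per the labels, the controls were Wistar-Kyoto rats, a normotensive laboratory strain. The strain entry of the hypertensive rats reads Wistar-Kyoto as well, although the series title sets Wistar-Kyoto controls against a hypertensive disease model, so the strain of the hypertensive group is not settled here. Which vessel was taken is not given in the sources used here. Group and replicate number came from the sample titles.

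Per the labels' protocols, total RNA was extracted with Trizol, 100 ng was labelled with Cy3, and the labelled RNA was hybridised to an Agilent rat expression array. The scanner files hold spot intensity values that Agilent Feature Extraction had already background-subtracted and processed, per the file headers. The file headers give version 10.7.1.1 of that program, while the submitters' processing notes give version 12.1.1.1. The deposited value table of the series holds a linear ratio. Set against the scanner values, it equals the processed intensity divided by a constant close to the 75th percentile of each array, with 0 probes above a value of 1 that deviate by over 5%. The medians of its 8 columns were 0.092, 0.089, 0.086 and 0.091 in control replicates 1 to 4 and 0.101, 0.093, 0.097 and 0.090 in hypertensive replicates 1 to 4. It was not centred on genes and holds no direction of its own. It served as an alternative only.

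Each array held 58717 gene spots for 45598 probes. Spots marked as non-uniform or population outliers (213 to 396 per array) were left out where another spot of the probe remained, and the rest were averaged per probe on the log2 scale. The array's 75th percentile over probes was then subtracted, so that all levels are log2 signal relative to that percentile. No gene spot was saturated. Of the probes, 58.7% to 64.1% per array were well above background (a mark set for each spot in the scanner files, required on 50% or more of a probe's spots), and the number of arrays limits the precision. A probe was kept where it was well above background on at least 3 of the 4 arrays of at least 1 group, which left 27822 probes.

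The scanner files carry accessions and no gene symbols. Symbols came from an NCBI table of rat genes (assembly GRCr8), matched on accession without version. The match named 21229 of the 45598 probes (46.6%), with 94.4% of probes for curated messenger RNA records and 20.4% of those for predicted ones. None of the 6336 probes with Ensembl transcript names could be named. No coordinates are printed, because the probes were not placed on a genome here. A gene was represented by its brightest kept probe, and an unnamed probe stood for itself, giving 24552 tests for 11965 named genes and 12587 unnamed probes. Of the 89 named genes past the threshold with at least 2 kept probes, 4 had another probe going the opposite way at an unadjusted p under 0.05.

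The groups were compared with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, group as the only term, all 8 arrays), with Benjamini-Hochberg adjustment and a threshold of an adjusted p under 0.05. Every adjusted p of a gene below is from this limma fit. The ± after a log2 change is the standard error of the limma fit with 4 arrays per group. Changes are hypertensive minus control. Where a probe was well above background on no array of a group, its level there is only a bound. The fold is then given as "at least", from the brighter group's mean. On each array of the dimmer group it uses the higher of the probe's own signal and the lowest signal among probes well above background. That lowest signal is not a detection limit for every probe, so these minimum folds hold for the processed signal only. Normexp background correction, whose offset of 50 shrinks changes of dim probes, gave changes below them for each such named gene past the threshold.

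Before the data were examined, 39 gene lists (934 members as written, 4 of them with no current symbol) were fixed for vessel wall cell types, other cell types the tissue could hold, and pathways of vessel function. Each list with at least 3 tested genes was tested with camera, the competitive gene set test of limma, with a preset correlation of 0.01. The test was repeated with an estimated correlation and with fry, a rotation test of whether the genes of a list move, on balance, one way. For each list the number of members past the threshold is given over all tests and adjusted over the list alone. A list's mean was also compared between the groups with a two-sided exact permutation test over the 35 ways of dividing 8 arrays into 4 and 4, which cannot give a p below 0.0286.

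The genes named were chosen by a rule fixed at the same time. It takes the 12 largest rises and 12 largest falls with a real symbol among genes past the threshold whose groups did not overlap. From each list it takes up to 4 members past the threshold by size of change, or the 2 with the smallest p where none passed. It also takes all tested members of a list of candidate genes of inherited rat hypertension. Some genes so chosen and some of the lists are not reported here, which leaves 98 genes. Any other gene named is said to have been chosen after its values were seen.

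The method was tested on simulated data made from the means and spreads of the 24552 tests, with 200 changed genes. At a log2 change of 0.5, 31.3% were recovered, at 1 70.1% and at 2 95.5%. Of 24312 unchanged genes 4 were called. Both lists given a shift of 0.5 were called, and none of the other lists. The simulated genes were drawn independently of each other. The simulation therefore does not test how often camera calls lists whose genes move together, as in real tissue. It also changed fewer genes than the 1111 called in the data. The Benjamini-Hochberg cut-off depends on the share of changed genes, so recovery in the data may differ.

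All 8 arrays lay on 1 slide and shared 1 scan. The control arrays filled row 1 of the slide and the hypertensive arrays row 2, so slide row and group cannot be told apart. The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, other filters on detection, the value table, eBayes with a trend and robust variance, array weights, the mean of a gene's probes, the replicate number as a block, other thresholds, a plain equal-variance test, other list tests and each array left out in turn. Normexp was run on the median spot signal, since the files hold no mean signal. After the data were seen, 1 alternative was added, the mean of the white adipocyte list as a covariate.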

Results

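Gene expression was measured in vessels of 4 control and 4 hypertensive male rats, with 1 array per animal. The question was how vessels of a hypertensive rat model differ from those of control rats in their transcripts. The 75th percentile of the processed signal was 405 to 503 in the control arrays and 357 to 478 in the hypertensive arrays. The first principal component carried 42.4% of the variance and separated the groups, with scores of -34.1 to -27.7 for the controls and 24.0 to 35.1 for the hypertensive rats. The second carried 17.0% and set hypertensive replicate 4 (-44.6) apart from the other 7 arrays (-12.0 to 24.9). Across genes, Pearson correlations were 0.993 to 0.994 between control arrays, 0.987 to 0.992 between hypertensive arrays and 0.983 to 0.987 between the groups. Genes are not independent replicates.

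Vessels of hypertensive rats gave far more signal for the neuronal sodium channel gene Scn1a and the heavy neurofilament gene Nefh, each read by 1 kept probe, and less for immediate early genes such as Fosb and for the chemokine genes Cxcl1 and Cxcl2. In all, 641 genes or unnamed probes were higher and 470 lower in hypertensive vessels among 24552 tested (1111, or 4.53%, at an adjusted p under 0.05). Of these, 254 named genes were higher and 246 lower. A change of at least 2-fold was found for 232 higher and 176 lower. The groups did not overlap for 1103 of the 1111, and for 13.6% of all tests, where chance gives 2.86%. The count fell to 629, 725 and 695 without control replicates 1, 2 and 3 and to 688 without hypertensive replicate 2, and was 1473 without hypertensive replicate 4. Of the 55 named genes that passed and are described below, 23 lost their call when some 1 array was left out, and 28 with a plain equal-variance test, which called 593 in all. Quantile normalization turned the split to 529 higher and 586 lower.

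**Figure D1:**
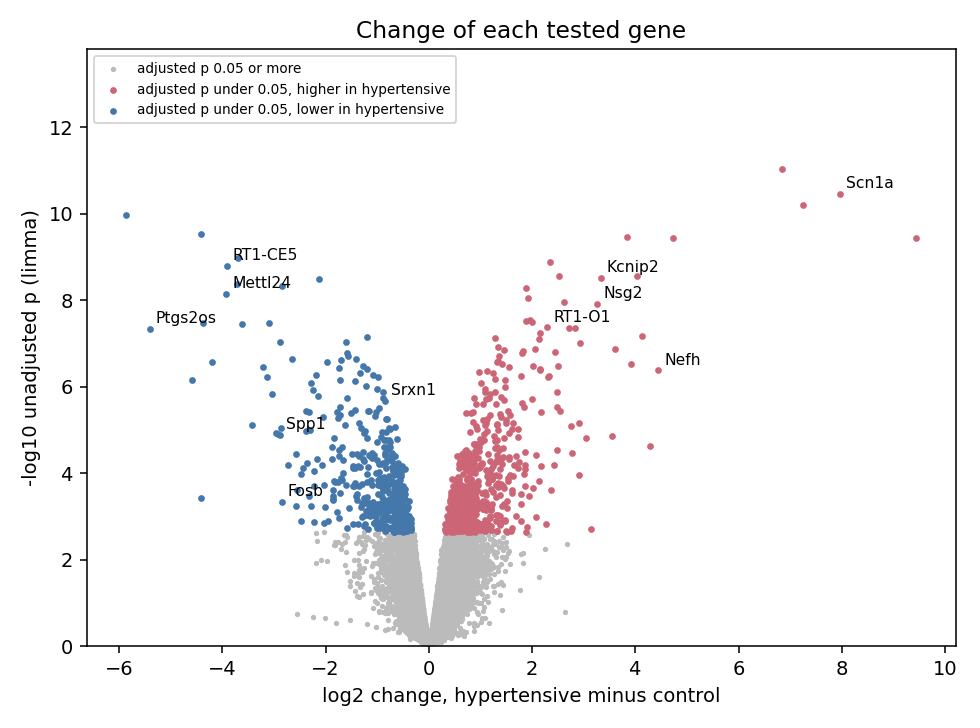
Log2 change (hypertensive minus control, n = 4 arrays each) against -log10 of the unadjusted limma p for each of the 24552 tests, with the 641 higher in red and the 470 lower in blue. Changes of probes near background in 1 group, such as Scn1a, are fitted values and not bounds.

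Among genes with an established symbol, the rise of Scn1a was the largest, at least 100-fold on the processed signal (adjusted p = 4.2e-07). A gene known only by the database symbol RGD1309362, chosen after its values were seen, rose by 9.44 ± 0.31, and by 7.67 on its second kept probe, with 1 of 4 control arrays above background. The level of Scn1a was 0.78 ± 0.29 (SD, n = 4) in hypertensive vessels, and it was not well above background on any control array. Nefh was also above background only in the hypertensive group, at least 13-fold higher (adjusted p = 0.00015). Kcnip2, which encodes a subunit that binds Kv4 potassium channels, rose by a log2 change of 3.33 ± 0.14 (10.1-fold), and Nsg2, a neuronal vesicle protein gene, by 3.26 ± 0.16 (9.58-fold). Smr3b rose by 4.28 ± 0.53, from a level that only 2 of 4 control arrays measured above background. Tuft1 rose by 2.72 ± 0.16, Myoc (myocilin, a secreted glycoprotein) by 2.49 ± 0.32 and RT1-O1, of the rat major histocompatibility complex, by 2.29 ± 0.13. Mtmr7, Dmp1 and Zp2 were above background in no control array and rose at least 3.17-fold, 2.52-fold and 1.55-fold, with Dmp1 and Zp2 measured on 3 of 4 hypertensive arrays. Myh1, a fast skeletal myosin heavy chain, rose by 2.28 ± 0.50 (adjusted p = 0.040), a call lost without any 1 of 7 arrays (all but hypertensive replicate 2). With normexp background correction the log2 change was 3.70 for Scn1a, 1.48 for Nefh, 2.02 for Smr3b, 1.59 for Tuft1, 1.52 for RT1-O1, 0.55 for Mtmr7, 0.51 for Dmp1, 0.56 for Zp2 and 0.83 for Myh1, all past the threshold.

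The largest fall among named genes was that of Ptgs2os, a transcript antisense to the cyclooxygenase gene Ptgs2. On the processed signal Ptgs2os was at least 31.9-fold lower in hypertensive vessels (adjusted p = 3.5e-05). Ptgs2 itself fell by 1.05 on the log2 scale (SE 0.22, adjusted p = 0.031), a call lost without any 1 of 5 arrays (control replicates 1, 3 and 4 and hypertensive replicates 3 and 4). Mettl24 and Hba-a3, a haemoglobin alpha gene, were above background in no hypertensive array, at least 4.53-fold and 3.49-fold lower. RT1-CE5, a class I histocompatibility gene, was measured on all 8 arrays and changed by -3.91 ± 0.15 (15.1-fold lower), and like Ptgs2os was read by 1 kept probe. Hsd17b13, a lipid droplet protein gene, changed by -2.88 ± 0.18. Spp1, which encodes osteopontin, changed by -2.88 ± 0.33 and Slc7a14 by -2.56 ± 0.43, both above background on 2 of 4 hypertensive arrays. Garin4 changed by -4.40 ± 0.79 with 1 of 4 hypertensive arrays above background, and lost its call without control replicate 1. With normexp background correction the log2 change was -2.31 for Ptgs2os, -1.43 for Garin4, -0.65 for Mettl24, -0.58 for Hba-a3, -1.17 for Hsd17b13, -0.76 for Spp1 and -0.61 for Slc7a14, all past the threshold. Hba-a3 and the RT1 genes have close relatives in the genome whose transcripts could bind the same probe, so which family member changed is uncertain.

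**Figure D2:**
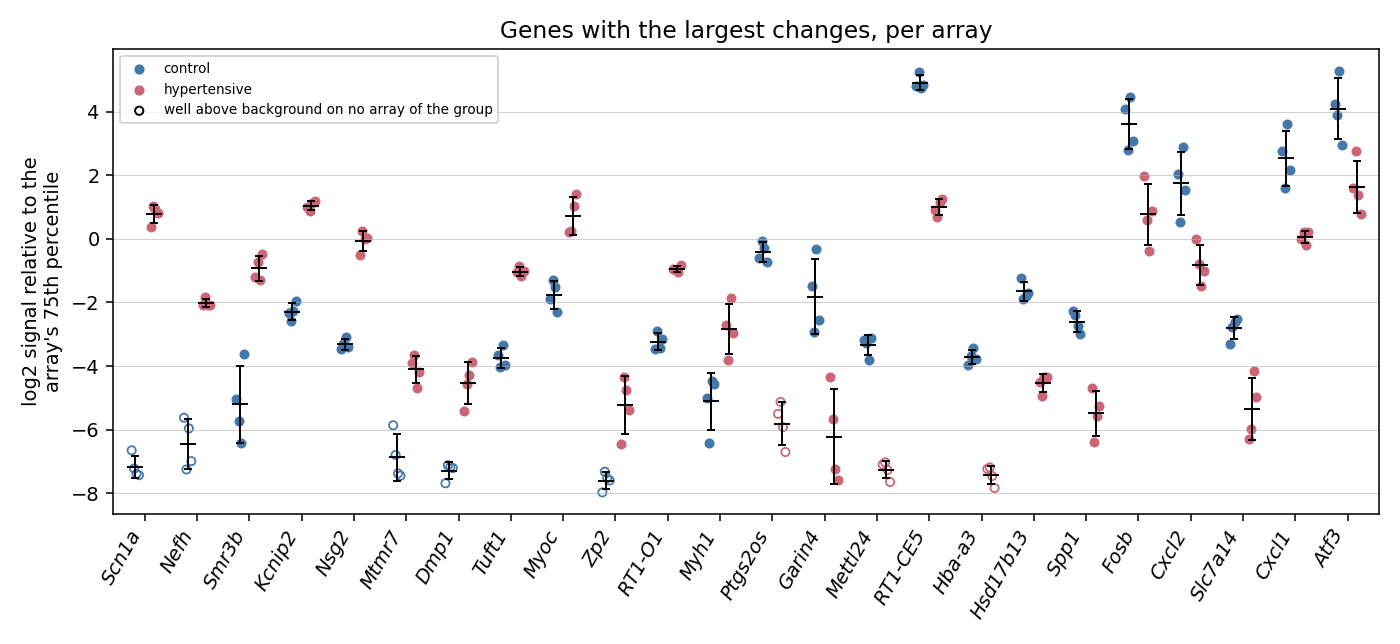
Log2 signal relative to the array's 75th percentile for the 12 largest rises and 12 largest falls among genes with an established symbol, with a point per array, group mean and SD (n = 4). Open points mark groups in which the probe was well above background on no array, as for Scn1a in the controls and Ptgs2os in the hypertensive group.

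Immediate early genes, which cells switch on within minutes of a stimulus, were lower in hypertensive vessels. Of 24 tested, 14 fell, none rose and 10 were not past the threshold. Adjusted over the list alone, 18 fell. Fosb changed by -2.85 ± 0.53, Atf3 by -2.47 ± 0.53, Nr4a1 by -2.03 ± 0.44 and Dusp1, a phosphatase that shuts off MAP kinases, by -1.83 ± 0.21 (adjusted p = 0.019, 0.036, 0.039 and 0.0020). The list's median log2 change was -0.99, and all 4 hypertensive arrays had a lower list mean (-0.81 to -0.32) than all 4 controls (0.25 to 1.08; exact permutation p = 0.0286, the smallest the design allows, 0.279 adjusted over 39 lists). The camera test gave an adjusted p of 1.4e-14, and an adjusted p = 0.841 with an estimated correlation. The number of members that fell was 4 without control replicate 1, 7 without control replicate 3 and 6 without hypertensive replicate 3, 3 with the replicate block and 1 with a plain equal-variance test. Without hypertensive replicate 4, 12 fell and 1 rose. Fosb, Atf3 and Nr4a1 each lost their calls without some single arrays, while Dusp1 kept its call without any 1 array.

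Several inflammatory cytokine and chemokine genes fell as well. Of 25 tested, 8 fell, none rose and 17 were not past the threshold. Adjusted over the list alone, 11 fell and 3 rose. Besides Spp1, the neutrophil chemokine genes Cxcl2 and Cxcl1 changed by -2.57 ± 0.49 and -2.47 ± 0.37, and the interleukin gene Il1b by -1.49 ± 0.20 (adjusted p = 0.022, 0.0071 and 0.0038), with the Cxcl2 call lost without control replicate 1 or hypertensive replicates 2 or 3. The list's median change was -0.28 (camera adjusted p = 0.00022, adjusted p = 0.841 with an estimated correlation; exact permutation p = 0.0286, 0.279 adjusted). The median was -0.57 without control replicate 1, -0.52 without hypertensive replicate 4, -0.49 without the detection filter, -0.46 with the adipocyte covariate and -0.17 with normexp. The number that fell was 5 without control replicate 1 or without hypertensive replicate 3, 5 with the replicate block and 4 with a plain equal-variance test, which also ended the calls of Cxcl1 and Cxcl2. Among 23 complement and coagulation genes, C4a (-1.25 ± 0.17) and C4b (-0.93 ± 0.18) fell, and since these 2 genes are near-identical, which of them fell is uncertain. The C4b call, unlike that of C4a, was lost with some single arrays left out. Adjusted over the list alone, 2 fell and 1 rose.

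Of 11 mast cell markers, 1 was past the threshold, the proteoglycan gene Srgn (1.22 ± 0.19, adjusted p = 0.0087), and 8 rose adjusted over the list alone. Its median change was 0.72 (camera adjusted p = 0.0067, adjusted p = 0.888 with an estimated correlation), and the camera call was lost without hypertensive replicate 4 (adjusted p = 0.066) and with the white adipocyte list as a covariate, an alternative chosen after the data were seen (median 0.45, adjusted p = 0.072). Of 19 lymphocyte markers none passed, with Cd3d at -0.74 ± 0.18 and Il7r at -0.66 ± 0.18 (adjusted p = 0.053 and 0.080), although 4 were lower adjusted over the list alone and camera gave 0.042 (adjusted p = 0.888 with an estimated correlation). That call was lost in 5 of the 8 tests with 1 array left out, with adjusted p up to 0.353 without hypertensive replicate 3, and with quantile normalization, median centring, detection on all 8 arrays or the replicate block. The exact permutation p of the lymphocyte mean was 0.571, and 17 of the 35 divisions of the arrays, the real one included, gave a camera p as small. Of 19 macrophage and monocyte markers the mannose receptor gene Mrc1 fell (-0.51 ± 0.12, adjusted p = 0.0496, lost without any 1 array but hypertensive replicate 4, and with normexp at -0.25), with 4 lower and 1 higher adjusted over the list alone. Of 15 nerve and Schwann cell markers only Nefh passed, and 3 rose adjusted over the list alone (camera adjusted p = 0.189, fry 0.040).

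None of the 21 white adipocyte and lipogenesis genes passed, by either adjustment, the smallest p being those of Acly (0.24 ± 0.07) and Elovl6 (0.51 ± 0.16). Hypertensive replicate 4 had a list mean of 1.26, against -0.44 to 0.06 in the other hypertensive arrays and -0.51 to 0.14 in the controls. The list's median change was 0.29 (camera adjusted p = 0.156, adjusted p = 0.888 with an estimated correlation). It was 0.10 without hypertensive replicate 4 (adjusted p = 0.929), 0.17 with array weights, 0.51 without control replicate 3 and 0.58 without hypertensive replicate 2, where the list passed camera (adjusted p = 0.013). The same array was highest of all 8 in its means of the mast cell (0.71), lymphocyte (0.61), erythroid (0.56), brown adipocyte (0.51) and macrophage and monocyte (0.26) lists. None of 10 brown adipocyte markers passed by either adjustment, with Fabp3 at -0.33 ± 0.12 and Cpt1b at 0.48 ± 0.21. Of 17 skeletal or cardiac muscle markers Myh1 rose and myoglobin, Mb, fell (-0.54 ± 0.12, lost without hypertensive replicate 1 or any 1 control), with 2 higher and 1 lower adjusted over the list alone. Of 6 erythroid markers Epb42 rose (0.74 ± 0.12, and 0.39 with normexp), by both adjustments.

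**Figure D3:**
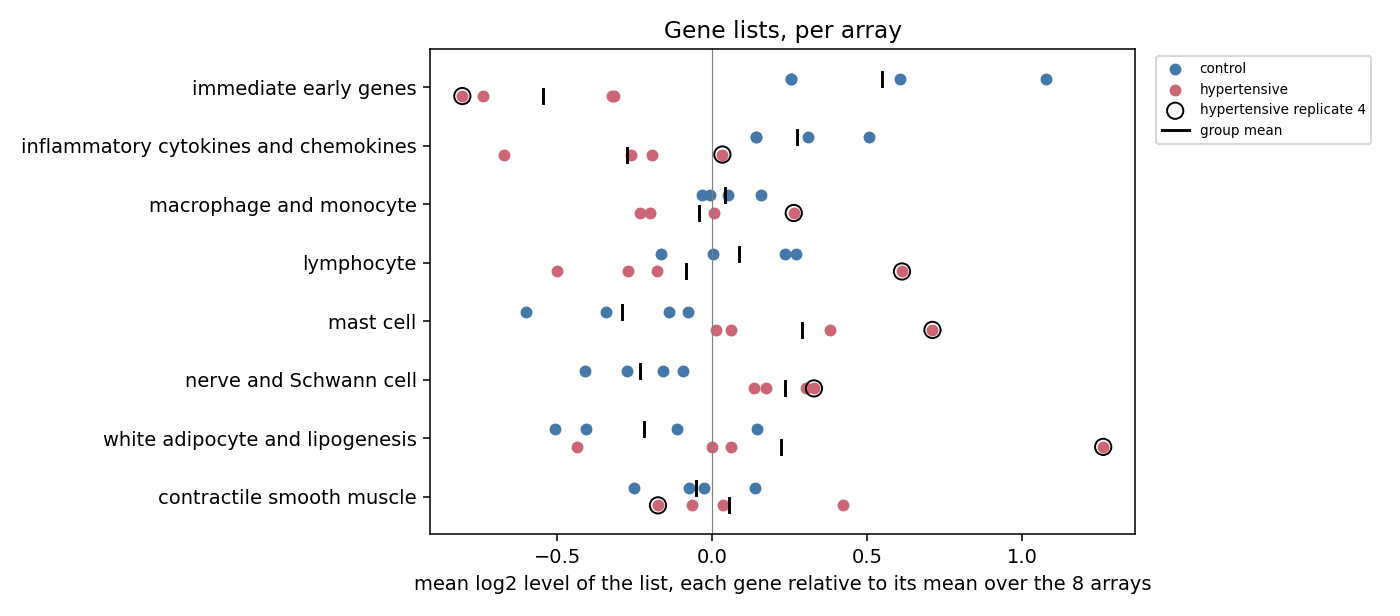
Mean log2 level of 8 gene lists on each array, each gene taken relative to its mean over the 8 arrays, with group means as bars (n = 4). The immediate early means of the hypertensive arrays (-0.81 to -0.32) lie below those of the controls (0.25 to 1.08), and the circled hypertensive replicate 4 stands at 1.26 for the white adipocyte list.

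Counts for genes of the vessel wall itself follow. Since 4.53% of all tests passed, small counts in lists of this size do not set the wall apart from other genes. Of 19 contractile smooth muscle genes, 1 passed, the myosin light chain gene Myl9 (-0.45 ± 0.10, adjusted p = 0.048). Of 21 fibrillar collagen and crosslinking genes, the prolyl hydroxylase gene P4ha3 rose (1.54 ± 0.24, with 1 of 4 control arrays above background, and 0.38 with normexp). Of 15 elastic fibre genes, Ltbp2 rose (1.31 ± 0.31) and Mfap2 fell (-0.76 ± 0.17). Each of these counts was the same adjusted over the list alone. The calls of Myl9, Ltbp2 and Mfap2 were each lost without some single arrays, while that of P4ha3 was not. Of 16 matrix proteases and inhibitors, the protease gene Adamts1 fell (-1.18 ± 0.22), by both adjustments, a call lost without control replicate 1 or hypertensive replicates 2 or 3. That list's median was -0.16 (camera adjusted p = 0.030, adjusted p = 0.841 with an estimated correlation), and its call was lost without control replicate 2 or hypertensive replicates 2 or 3 (0.063, 0.091 and 0.107). The median was -0.25 without hypertensive replicate 1 and -0.26 with the adipocyte covariate. None of 10 basement membrane genes passed over all tests and 1 was lower adjusted over the list alone, with Nid2 at -0.36 ± 0.10 and Lamb2 at -0.28 ± 0.13. None of 16 endothelial markers passed (Cldn5 -0.43 ± 0.11, Eng -0.32 ± 0.09), nor of 15 fibroblast and adventitia markers (Ly6c -0.53 ± 0.16, Htra3 -0.36 ± 0.13), by either adjustment.

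Of 28 calcium handling genes, the cation channel genes Trpc4 (at least 1.97-fold, with 3 of 4 hypertensive and no control array above background) and Trpc6 (1.01 ± 0.22) rose, and the inositol trisphosphate receptor gene Itpr3 fell (-0.35 ± 0.08), by both adjustments (camera adjusted p = 0.650). Of 19 potassium and chloride channel genes, Kcnmb1, the smooth muscle subunit of the large-conductance calcium-activated potassium channel, rose (0.82 ± 0.11, adjusted p = 0.0050), and 3 rose adjusted over the list alone (camera adjusted p = 0.223). Of 22 nitric oxide and cyclic nucleotide genes, the phosphodiesterase gene Pde1b fell (-0.75 ± 0.16), by both adjustments. Of 19 arachidonic acid and prostanoid genes Ptgs2 fell, and 2 fell adjusted over the list alone. By either adjustment, none of 32 vasoactive receptors and ligands passed (P2ry2 -0.38 ± 0.11, Adra1a 1.05 ± 0.32, with a second Adra1a probe at -0.02). The calls of Trpc6, Itpr3 and Pde1b were each lost without some single arrays, and those of Trpc4 and Kcnmb1 were not. With normexp the change was 0.30 for Trpc4 and -0.47 for Pde1b, both past the threshold.

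None of 16 angiotensin and aldosterone genes passed, by either adjustment, with Cma1, mast cell chymase, at 0.82 ± 0.24 and Hsd11b2 at 0.67 ± 0.22 (adjusted p = 0.092 and 0.124). Of 18 tested candidate genes of inherited rat hypertension, 1 passed over all tests and adjusted over the list alone. It was Acsm3, an acyl-CoA synthetase gene (0.64 ± 0.13, adjusted p = 0.031), and the call was lost without control replicates 2, 3 or 4 or hypertensive replicates 1, 2 or 3. With normexp its change was 0.34. The angiotensin receptor gene Agtr1b differed by 1.77 ± 0.78, Cd36 by 0.52 ± 0.23, Adra1d by -0.78 ± 0.25, Endog by -0.65 ± 0.24 and Agt by -0.56 ± 0.37, none past the threshold. The rest reported here lay between -0.26 (Folr1) and 0.44 (Spon1), with Ace at 0.12 ± 0.14, Stim1 at 0.22 ± 0.14, Gstm1 at 0.31 ± 0.12, Ptger4 at 0.38 ± 0.13, Vav2 at 0.19 ± 0.10, Ogn at 0.07 ± 0.09, Sod3 at -0.08 ± 0.09, Srebf1 at 0.06 ± 0.16 and Ndufc2 at -0.0045 ± 0.12. The kept probes of Ace and of Srebf1 differed in sign.

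Of 31 NADPH oxidase and antioxidant genes, 2 that answer to oxidative stress fell, the haem oxygenase gene Hmox1 (-0.86 ± 0.16) and the sulfiredoxin gene Srxn1 (-0.85 ± 0.08, adjusted p = 0.00047). Catalase, Cat, rose (0.57 ± 0.11). The calls of Hmox1 and Cat were each lost without some single arrays, and that of Srxn1 was not. Adjusted over the list alone, 3 fell and 1 rose. The list's median was -0.08 (camera adjusted p = 0.042, adjusted p = 0.888 with an estimated correlation), and its call was lost without control replicates 2 or 3 or hypertensive replicates 2 or 3 (adjusted p of 0.129, 0.082, 0.091 and 0.107), and with median centring or the replicate block. The median was -0.040 and -0.047 without control replicates 3 and 2, -0.050 without hypertensive replicate 1 and -0.050 with array weights. None of 18 glutathione transferase genes passed by either adjustment (Gstm2 -0.49 ± 0.14, Gstm5 -0.35 ± 0.14). Of 22 heat shock and unfolded protein response genes the pseudokinase gene Trib3 rose (1.64 ± 0.25, by both adjustments, and 0.60 with normexp).

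Of 23 glycolysis genes the lactate transporter gene Slc16a3 rose (0.86 ± 0.09, adjusted p = 0.00075), by both adjustments. None of 34 oxidative phosphorylation genes passed over all tests, while 3 were lower adjusted over the list alone (Atp5f1b -0.34 ± 0.08, Cox5a -0.34 ± 0.08). None of 22 cholesterol biosynthesis genes passed by either adjustment (Acat2 0.30 ± 0.09, Msmo1 0.30 ± 0.11), and the 4 kept probes of Acat2 differed in sign.

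Among 18 antigen presentation genes RT1-Bb (1.55 ± 0.21) and RT1-A1 (0.73 ± 0.10) rose and RT1-CE5 fell, and 4 rose and 1 fell adjusted over the list alone. None of 23 interferon response genes passed over all tests, with 1 rising and 1 falling adjusted over the list alone (Ifi27 -0.35 ± 0.09; Ifit1 at least 2.29-fold, adjusted p = 0.070, with no control and 3 of 4 hypertensive arrays above background). Of 22 cell cycle genes the spindle gene Tpx2 rose (0.74 ± 0.15, and 0.30 with normexp) and the replication helicase gene Mcm2 fell (-0.44 ± 0.09), with 1 rising and 2 falling adjusted over the list alone. None of 30 TGF-beta and BMP genes passed by either adjustment (Id1 -0.57 ± 0.15; camera adjusted p = 0.183, fry 0.040). None of 15 circadian clock genes passed by either adjustment (Bhlhe40 -0.74 ± 0.25, Nfil3 -0.76 ± 0.47). Of 26 Notch and vascular patterning genes the angiopoietin gene Angpt2 fell (-0.53 ± 0.10), by both adjustments. The calls of Tpx2, Mcm2 and Angpt2 were each lost without some single arrays.

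In total 6 of the 39 lists passed camera, those of immediate early genes, cytokines, mast cells, matrix proteases, lymphocytes and NADPH oxidase and antioxidant genes. Of the 35 ways to divide the 8 arrays into 4 and 4, 27 (the real one included) gave at least 6 lists. None passed with an estimated correlation (adjusted p of 0.841 or more), and fry called 3, immediate early genes, TGF-beta and BMP signalling and nerve and Schwann cells. The exact permutation p of the list mean was 0.0286 for immediate early genes, cytokines, mast cells and nerve and Schwann cells. It was 0.057 for matrix proteases, 0.114 for NADPH oxidase and antioxidant genes and 0.571 for lymphocytes. Adjusted over the 39 lists, no exact permutation p passed, the smallest being 0.279. The median of a list and the direction of its test differed for basement membrane, endothelial, brown adipocyte, vasoactive, nitric oxide, glutathione transferase and circadian genes, whose medians were above 0 while the test pointed down. For interferon response and angiotensin genes the mean was above 0 and the median and test were below. None of these lists passed.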

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

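The tests of cell types, single arrays, handling and array brightness given here were chosen after the results were seen. The immune cell test first asked whether the immediate early mean lay below the lower end of the lymphocyte interval (-0.81), which it did, and its form was revised after that, and once more to ask that the result hold with any 1 array left out. The counts of genes and of lists over divisions of the arrays were set before. The counts of divisions for single lists were not among them. Within a group of 4 arrays, 13 of 286 group values looked at had 1 array far from the other 3 (a gap beyond Dixon's 95% critical value; 4.55%, where chance gives about 1 in 20). Among genes past the threshold, Nefh stood at -1.83 in hypertensive replicate 2 (others -2.09 to -2.07). Dmp1 stood at -7.69 in control replicate 1 (-7.21 to -7.12), but it was well above background on no control array, so this gap lies at the floor. Mb stood at -0.89 in control replicate 2 (-0.78 to -0.76) and Epb42 at -2.88 in hypertensive replicate 3 (-3.27 to -3.22). Tpx2 stood at -4.69 in control replicate 2 (-5.05 to -4.99) and Trpc6 at -2.83 in control replicate 4 (-2.38 to -2.31). Among genes not past it, Lamb2 stood at 4.06 in control replicate 1 (3.65 to 3.67), Ifi27 at 4.71 in control replicate 2 (4.50 to 4.51) and at 4.05 in hypertensive replicate 4 (4.25 to 4.29), and Atp5f1b at 3.14 in control replicate 3 (3.25 to 3.26). Endog stood at -1.02 in control replicate 2 (0.02 to 0.09). In control replicate 2 the mean of the fibroblast and adventitia list was 0.20 (others -0.02 to -0.00034), and that of the antigen presentation list 0.29 (others -0.03 to 0.02).

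Of the 35 ways to divide the 8 arrays into 4 and 4, only 1, the real one, called 1111 genes, and the highest of the others called 1. A rank of 1 in 35 is the smallest share the design allows, so chance is made less likely but is not excluded. The other divisions mix the groups, so a group difference widens their spread and lowers their counts. The real division also matches the rows of the slide. For lists, 27 of the 35 divisions, the real one included, had at least 6 lists past camera, and the highest had 18. Chance is not excluded for the number of lists. The camera p of the immediate early list was as small in 2 of the 35 divisions and that of the cytokine list in 3, the real one included.

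The fall of immediate early genes (mean change -1.09, 95% interval -1.67 to -0.52) was weighed against a loss of immune cells. Their mean change lay below that of the macrophage list by 1.01, with the upper end of the 95% interval at -0.30, and at -0.37 to -0.091 with 1 array left out. This argues against a loss of macrophages as the whole of the fall. A smaller loss stays open, as the macrophage list's own mean change had a 95% interval of -0.38 to 0.21. Its mean was highest of all 8 arrays in hypertensive replicate 4 (0.26), and it passed camera, as lower, with the adipocyte covariate. A loss of lymphocytes stays open, as the difference from the lymphocyte list, -0.92, had its upper end at -0.0198, and above 0 in 5 of the 8 fits with 1 array left out (up to 0.26), and was -0.60 without hypertensive replicate 4. No single array made the fall of the immediate early list itself, as its mean change kept at least 83.9% of its size with any 1 array left out. A difference in how vessels were handled between death and freezing may also move these genes, and cannot be told apart from the groups, since no label records handling and the groups lay apart by a gap of 0.57, and an effect of hypertension itself stays open, untested.

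Hypertensive replicate 4 stood apart on the second principal component. Of the 21 white adipocyte and lipogenesis genes, 90.5% were higher there than in every other hypertensive array, against 24.5% of all tested genes, with a median difference of 1.05 from the mean of the other 3. Abundant fat cell transcripts were among them, with Adipoq higher by 3.58, Fabp4 by 2.09 and Cfd by 1.68 (chosen after their values were seen). This is consistent with more fat tissue in that sample, as a hypothesis, though several list members, such as Fasn and Srebf1, are expressed in other cells too. A dim array is argued against by its 63.2% of probes well above background, inside the range of the other 7 arrays, and a difference of that animal stays open.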

How the results depend on the processing

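The covariate alternative was chosen after the data were seen, the others before. Changes are log2, hypertensive minus control. The 1111 changed genes (641 higher, 470 lower) became 1853 with normexp (1199 higher; 654 lower), 641 with no detection filter (375 and 266, with 41047 tests), 593 with a plain equal-variance test (330 and 263), 416 at an adjusted p under 0.01 (233 and 183) and 408 at 2-fold or more (232 and 176). With 1 array left out they ranged from 629 to 1473 (higher 379 to 853, lower 247 to 620), with fewer samples. With normexp 5 of the 1111 turned sign, and under the other refits none did. The median change of all genes moved from 0.04 to 0.0015 with quantile normalization, which gave 529 higher and 586 lower. The replicate numbers are not said to pair the animals, but in both groups they match the column of the slide. Same-numbered arrays had deviations correlated at 0.21, 0.12, -0.0035 and -0.15, and not every array correlated best with its own number. So few correlations cannot decide whether the arrays are paired, and the replicate block is also a block of slide column. With the replicate block 675 genes passed (381 and 294), and 3 of the immediate early genes. Without the detection filter 7 of 25 immediate early genes fell.

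The 6 lists past camera became 13 with normexp, 12 with no detection filter, 0 with an estimated correlation, 3 with fry, and 3 to 9 with 1 array left out. The immediate early list passed in 21 of 22 alternatives and the cytokine list in 20, the mast cell list in 18, matrix proteases in 17, NADPH oxidase and antioxidant genes in 14 and lymphocytes in 11. With the adipocyte covariate 1352 genes and 9 lists passed, macrophage and monocyte markers among them (median -0.21, adjusted p = 0.0014), and the mast cell list did not (median 0.45, adjusted p = 0.072). Without some single arrays collagen, elastic fibre, macrophage, white adipocyte, complement, glutathione transferase, oxidative phosphorylation and cholesterol lists passed too. The cause of these differences was not tested, beyond what fewer samples or more tests bring.

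Of the 55 named genes past the threshold, 25 stayed past it in each of the refits run on them (the stricter thresholds aside), and none turned sign. With a plain equal-variance test 28 lost the call, among them Zp2, Slc7a14, Cxcl1, P4ha3, Srgn, Trib3 and Trpc4, which kept it with any 1 array left out. With at least 1 array left out 23 lost it, namely Myh1, Garin4, Fosb, Cxcl2, Atf3, Myl9, Ltbp2, Mfap2, Adamts1, Mrc1, Mb, Tpx2, Mcm2, C4b, Nr4a1, Pde1b, Ptgs2, Trpc6, Itpr3, Hmox1, Cat, Angpt2 and Acsm3. Without control replicate 1, 21 of the 55 were lost, and without hypertensive replicate 4, 5. Genes dim in 1 group are limited by signal over background. With normexp 24 of the 55 had a change over 1.5 times smaller, of which 23 were past the threshold, all but Mrc1. Its offset of 50 compares with median processed signals of 35.8 to 43.5 per array. Such an offset makes the changes of dim probes smaller by construction, so this shrinkage does not measure their true size. In the other refits with all 8 arrays no named call moved by so much.

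Directions turned for the genes and lists that follow, none of them past the threshold in the values reported above. With the mean of kept probes Acat2 was at -0.0017, Ace at -0.0076 and Srebf1 at -0.0062. With array weights Srebf1 was at -0.053 and Ndufc2 at 0.057, with the covariate -0.074 and 0.012, and with 1 array left out -0.054 to 0.15 and -0.071 to 0.079. For lists the direction of the test turned, at these medians. With normexp these were contractile 0.077, brown adipocyte 0.10, calcium 0.053, glycolysis -0.010 and candidate genes 0.071. With no filter they were contractile 0.095, brown adipocyte 0.21, muscle 0.13, cell cycle 0.11, calcium 0.064, glycolysis 0.015, Notch 0.097 and candidate genes 0.063. With detection on all 8 arrays they were brown adipocyte 0.14 and muscle 0.062. With fry they were endothelial 0.062, brown adipocyte 0.043 and vasoactive 0.066. With array weights they were cell cycle 0.063 and glycolysis -0.0025, and with the mean of probes glycolysis 0.0097. With the covariate they were white adipocyte 0.073, muscle 0.11, erythroid -0.0071, cell cycle 0.034 and glycolysis -0.026. The covariate is the mean of the white adipocyte genes, Srebf1 among them, so it removes that list's mean change by construction. The turn of that list with the covariate was therefore built in, and that of Srebf1 is little evidence. With 1 array left out the medians ranged from -0.038 to 0.16 (contractile), 0.014 to 0.11 (endothelial), -0.0028 to 0.14 (brown adipocyte), 0.049 to 0.17 (erythroid), 0.043 to 0.18 (cell cycle), -0.21 to 0.095 (antigen presentation), 0.0015 to 0.090 (vasoactive), -0.018 to 0.032 (glycolysis) and 0.083 to 0.15 (Notch).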

Other observations

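Genes of the RT1 complex, the major histocompatibility complex of the rat, were looked at as a family after RT1-O1 and RT1-CE5 had been seen among the largest changes. Of 34 tested RT1 genes, 14 rose, 2 fell and 18 were not past the threshold. RT1-CE4 rose by 1.28 ± 0.10 and RT1-CE13 by 1.13 ± 0.12, while RT1-T24-4 changed by -2.13 ± 0.09. Of class II genes, RT1-Bb rose by 1.55 ± 0.21, while RT1-Da (0.0052 ± 0.23) and RT1-Db1 (-0.36 ± 0.23) did not pass. Over the alternatives 11 to 16 rose and 2 to 5 fell, with 5 falling under normexp and 4 without hypertensive replicate 4. Class I genes are near-identical, and their probes may read several of them.

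The probe test in this paragraph was set before its result was seen. So was the neighbour test of genes changed at least 2-fold in the next. The other neighbour sets there had no prediction set beforehand. Changes of at least 2-fold may come from a sequence variant under a probe rather than from a change in transcript. For 25 named genes with other kept probes, 90% of the 30 other probes changed the same way at an unadjusted p under 0.05 (exact 95% interval 73.5% to 97.9%). The interval takes the probes as independent, although some genes gave more than 1 and all were read on the same arrays. This argues against a variant under 1 probe for most of these genes, provided that their probes do not overlap, which was not checked. For the remaining 383 genes and unnamed probes, no second probe could be compared. The named genes, Scn1a and RT1-CE5 among them, had no second kept probe, and unnamed probes were not matched to each other. For all of these a variant cannot be told apart from a change in transcript level.

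A hypothesis is that the 2 groups differ in inherited blocks of the genome. Called genes would then lie next to each other more often than chance. Among 180 named genes changed at least 2-fold there were 6 neighbouring pairs with unlike symbols, against a mean of 2.57 in 10000 random draws (share of draws as high 0.046). All 500 changed named genes gave 28 pairs, against a mean of 19.7 (share 0.037). As many genes with the largest spread within groups gave 3 pairs (share 0.47). Adjusted over the 3 sets run, the shares were 0.070, 0.070 and 0.47. The first share lies just under the bound of 0.05 set beforehand and is consistent with inherited blocks, but it does not hold after adjustment, and genes that share regulation are also often neighbours. The pairs were Chi3l1 and Mybph, Atf3 and Garin4, Spp1 and Dmp1, Aplf and LOC100910604, Galnt6 and Slc4a8, and Frmpd4 and Prps2 (named after their values were seen). Spp1 fell while its neighbour Dmp1 rose.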
